A study of Mus musculus with 88 samples.

How the data were processed

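The deposited counts per gene and cell were used as the authors made them: per the labels, reads of a modified Smart-seq2 protocol on a NextSeq500 were aligned to mm10 with STAR 2.5b. The counting program, gene annotation, collapse of molecular identifiers and cell filter of the authors are not given in the sources used here. The lowest number of detected genes per deposited cell was between 323 and 435 in each pool. The deposited tables held 21135 cells and 79598240 counts, with 27407 genes in the time course and 27194 in the treatment experiment, of which 25919 were in both. Every column was matched to a library of the labels, with 0 columns unmatched. A set of 5 ribosomal RNA rows held from 20.81% of kept counts at Day 3 to 30.43% at Day 15.

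Groups, comparisons, gene lists, markers and the main cell and gene filters were chosen from the labels alone, before the data were examined. Other choices were made later, such as the naming rule below. Cells with at least 500 detected genes and at most 25% mitochondrial counts were kept, which left 19219 cells and 77779784 counts. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours were used for Leiden clustering at a resolution of 1.0 with scanpy 1.11.5. This gave 38 clusters, of which 37 were named as 12 classes by fixed markers. Class names rest on markers, so each class is one of cells that are like the named type. The naming rule of at least 3 markers at 2-fold, an override by the top 10 genes, and an exception for Krt5 and Krt14 were set after the clusters had been seen. Under that rule cluster 34, which held squamous markers (Krt14, Krt5) beside the mesothelial markers Upk3b and Msln, stayed unnamed. It held 4 cells at Day 0, 6 at Day 3, 4 at Day 6, 6 at Day 9, 5 at Day 12, 17 at Day 15, 6 with PBS, 3 with Serpina3n and 3 untreated. Scrublet with an expected rate of 5% marked only 0.0522% to 0.365% of cells per pool, too few to count as a working doublet filter. No doublets were removed, and doublets may remain in the classes.

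Counts were summed over the cells of a class in a pool and given as counts per total of the class (CPM). Log2 folds used a pseudocount of 1 CPM. A class was compared where both pools held at least 30 cells, and a library entered the spread where it held at least 5 cells of the class. The libraries are technical parts of 1 pool, so their SD is not a spread between mice and no test between groups was made. Poisson intervals of levels, exact binomial intervals of shares and conditional binomial intervals of ratios allow for counting error only. Those of levels and ratios treat reads as independent and may be too narrow. A gene met the size rule where it was at least 2-fold different and the difference of library means of log2(CPM+1) was larger than the sum of the 2 library SDs. Where a pool held 0 counts, the fold is given as at least the value reached with 3 counts. Genes were named for a class by rank, up to 5 highest and 5 lowest among those at 50 CPM or more in the higher pool that met the size rule. Immunoglobulin and T cell receptor segments, hemoglobin, mitochondrial, sex-linked and unnamed predicted genes were left out of this ranking, and not all ranked genes are described. Results of 2 list members are not reported here.

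Gene lists needed at least 5 members with a mean of 5 CPM or more, and the difference of a list is the median log2 fold of its members. The lists described are epithelial antimicrobial and acute phase, goblet and mucus, absorptive colonocyte, MHC class II and interferon-gamma response, type I interferon response, inflammatory cytokines and chemokines, collagens and matrix, matrix proteases and their inhibitors, epithelial niche factors, recruited monocyte, resident macrophage, complement, hypoxia and glycolysis, dissociation and immediate early, T cell effector and proliferation. The library SD of a list median was the yardstick within pools. Rank correlations between comparisons used genes with a mean of 20 CPM or more. Scaling by TMM (edgeR 4.0.16) and by DESeq2 1.42.0 was run beside scaling to the total.

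Sequence sharing was measured as the percent of 40-base words in the last 1000 bases of a gene that occur in another gene of GENCODE M21, and genes at 10% or more are given as uncertain. AI747448, Chi3l3, Clca3 and Ctgf had no match in this annotation and were not searched. A total of 10 gene symbols were matched through synonyms.

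The size rule was tested on simulated data in which gene counts were changed by known folds. For PBS against untreated it found 47.8% of 2-fold and 100% of 4-fold changes in fibroblasts, 40.3% and 100% in mononuclear phagocytes, 34.3% and 95.5% in epithelial cells, and 17.9% and 92.5% in T/NK/ILC. For Serpina3n against PBS in mononuclear phagocytes it found 44.8% of 2-fold and 100% of 4-fold changes. Of unchanged genes, 0 met the rule. These had the same mean in both simulated pools and varied between libraries only, so differences between runs or mice are not covered. Changed genes were drawn at a mean of 100 CPM or more, so the rates found do not hold for genes with fewer counts. A list of 20 unchanged genes gave medians of -0.13 in fibroblasts, -0.09 in mononuclear phagocytes, -0.24 in epithelial cells and -0.23 in T/NK/ILC for PBS against untreated, so list medians of this size are not read as differences. A list of 20 genes changed 2-fold gave medians of 0.87 in fibroblasts, 0.90 in mononuclear phagocytes, 0.81 in epithelial cells and 0.79 in T/NK/ILC, all below 1 on the log2 scale. The ratio intervals held the true ratio in 96.4% of 1000 draws. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, anndata 0.12.19 and R 4.3.3 were used.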

Results

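Single cells of mouse colon were sequenced in 9 groups, and each group was a single pool of tissue from 3 mice, so n = 1 pool per group. A set of 6 pools formed a time course of colitis caused by dextran sulfate sodium (DSS), a sulfated polysaccharide that injures the colon epithelium when it is given in drinking water. Per the labels, mice drank 1.5% DSS for 6 days and water from then on, and colon was collected at Days 0, 3, 6, 9, 12 and 15. The other 3 pools formed a treatment experiment with an untreated pool, a pool given DSS and injected with PBS, and a pool given DSS and injected with recombinant mouse Serpina3n, a secreted serine protease inhibitor. The 6 intravenous injections ran from Day 0 to Day 5, with Serpina3n at 20 µg/kg per day. PBS against untreated therefore holds the effects of DSS and of the injections together. Each pool was sequenced as 10 libraries, or 8 for Serpina3n, and these 88 libraries are technical parts of the pools. After filtering, 19219 of 21135 deposited cells were kept. Kept counts ranged from 6563352 at Day 9 to 12600994 at Day 3 per pool, and from 44235 in library 1 of Day 15 to 1544619 in library 1 of Serpina3n per library. With 1 pool per group no difference between groups has a replicate check, no p-value is given, and each SD is the spread over the libraries of a pool. All 95% intervals allow for counting error only. Those of gene levels and ratios treat reads as independent. PCR reads without stated molecular identifiers are not independent molecules, so these gene intervals may be too narrow even for counting error. Intervals of shares count cells, not reads. The untreated and Day 0 pools, neither of which had received DSS, came from different sequencing runs, and the difference between them is given as a yardstick for pools that should be alike. Day 9 and Day 0 shared a run prefix in the labels, and in the other comparisons named here run and group cannot be told apart.

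Over the time course, epithelial cells were a smaller share and mononuclear phagocytes (monocytes, macrophages and dendritic cells) a larger share of the colon cells from Day 3 to Day 9. Of all kept cells, fibroblasts were a smaller share, and neutrophils and B cells larger shares, from Day 6 onward. Fibroblasts, the matrix-producing cells of the colon wall, were 37.5% of cells at Day 0 (exact binomial 95% interval 35.3 to 39.7, library SD 6.56), 15.0% at Day 6 (13.7 to 16.4, SD 2.03), 10.1% at Day 9 (8.74 to 11.6, SD 1.93) and 6.88% at Day 15 (5.78 to 8.10, SD 5.75). Among stromal cells alone they were 78.1% at Day 0, 67.7% at Day 6, 64.4% at Day 9 and 77.2% at Day 15, so the Day 15 difference was not found within the stroma. Epithelial cells were 18.6% at Day 0 (16.9 to 20.4, SD 4.33), 6.06% at Day 6 (5.19 to 7.03, SD 1.34) and 10.9% at Day 9 (9.48 to 12.4, SD 3.22). Mononuclear phagocytes were 15.4% at Day 0 (13.8 to 17.1, SD 3.74), 42.0% at Day 6 (40.1 to 43.8, SD 6.03) and 37.5% at Day 9 (35.2 to 39.8, SD 11.2). These Day 6 and Day 9 differences from Day 0 were larger than the sum of the 2 library SDs. At Day 3 the epithelial difference of -8.87 and the mononuclear phagocyte difference of 12.0 percentage points were also beyond it, and at Days 12 and 15 those of both classes were within it. Among immune cells alone mononuclear phagocytes were 46.4% at Day 0, 58.6% at Day 6 and 51.3% at Day 9. At Days 12 and 15 they were 31.8% and 29.3% of immune cells, below Day 0. Neutrophils were 0 of 1917 cells at Day 0, with an exact binomial upper bound of 0.192%, and 9.48% at Day 9 (8.16 to 10.9, SD 4.10). B cells were 0.991% at Day 0 (0.598 to 1.54, SD 0.821), 7.10% at Day 6 (6.16 to 8.13, SD 3.77) and 24.0% at Day 15 (22.1 to 26.0, SD 14.3). Both of these immune classes hold few detected genes per cell, and with a minimum of 1000 in place of 500 detected genes the difference from Day 0 was 0.597 percentage points in place of 6.11 for B cells at Day 6 and 1.71 in place of 9.48 for neutrophils at Day 9.

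In the treatment experiment the fibroblast, mononuclear phagocyte and epithelial shares of the PBS pool lay on the same side of the untreated pool as those of Day 6 lay of Day 0. Of all kept cells, the share of the combined class of T cells, natural killer cells and innate lymphoid cells (T/NK/ILC) lay on the opposite side. The pool injected with Serpina3n held more epithelial cells and fewer B cells than the PBS pool. Against the untreated pool, the PBS pool held 19.1% fibroblasts (17.4 to 20.8, SD 3.07) in place of 38.5% (36.3 to 40.6, SD 4.07), 41.5% mononuclear phagocytes (39.4 to 43.6, SD 5.95) in place of 13.8% (12.3 to 15.4, SD 2.30), and 4.30% epithelial cells (3.49 to 5.23, SD 1.37) in place of 11.5% (10.1 to 13, SD 2.10). In the Serpina3n pool epithelial cells were 8.22% (6.99 to 9.59, SD 1.82), which is 1.91-fold the PBS share, and B cells were 3.07% (2.32 to 3.98, SD 1.23) against 7.68% (6.60 to 8.88, SD 3.21), a ratio of 0.400. Both differences were larger than the sum of the library SDs, and with 1000 detected genes the B cell difference was -0.964 in place of -4.61 percentage points. Fibroblasts at 15.4% (SD 5.38), mononuclear phagocytes at 41.1% (SD 4.05) and T/NK/ILC at 20.7% (SD 5.05) differed from the PBS pool by less than the library spread. Against the untreated pool, the T/NK/ILC share of the PBS pool was lower by 4.98 percentage points, beyond the sum of the library SDs, or higher by 1.91 with 1000 detected genes, and the B cell share was 5.09 points higher, within it. The T/NK/ILC share was 8.76% at Day 0 (SD 4.42) and 16.8% at Day 6 (SD 2.04), but among immune cells alone it was lower at Day 6, by -2.96 percentage points. Among immune cells alone it was also lower in the PBS pool, at 23.4% against 55.4% in the untreated pool. The opposite sides were thus found for shares of all kept cells and not among immune cells. Among stromal cells alone the fibroblast difference at Day 6 was -10.3 in place of -22.5 percentage points. Fibroblasts were 70.6% of the stromal cells of the PBS pool against 76.2% of those of the untreated pool. Between the untreated and Day 0 pools the T/NK/ILC share differed by 12.2, the epithelial share by -7.07 and the plasma cell share by -7.74 percentage points. The labels name flow sorting without its gates, so shares are those of sorted cells.

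**Figure D1:**
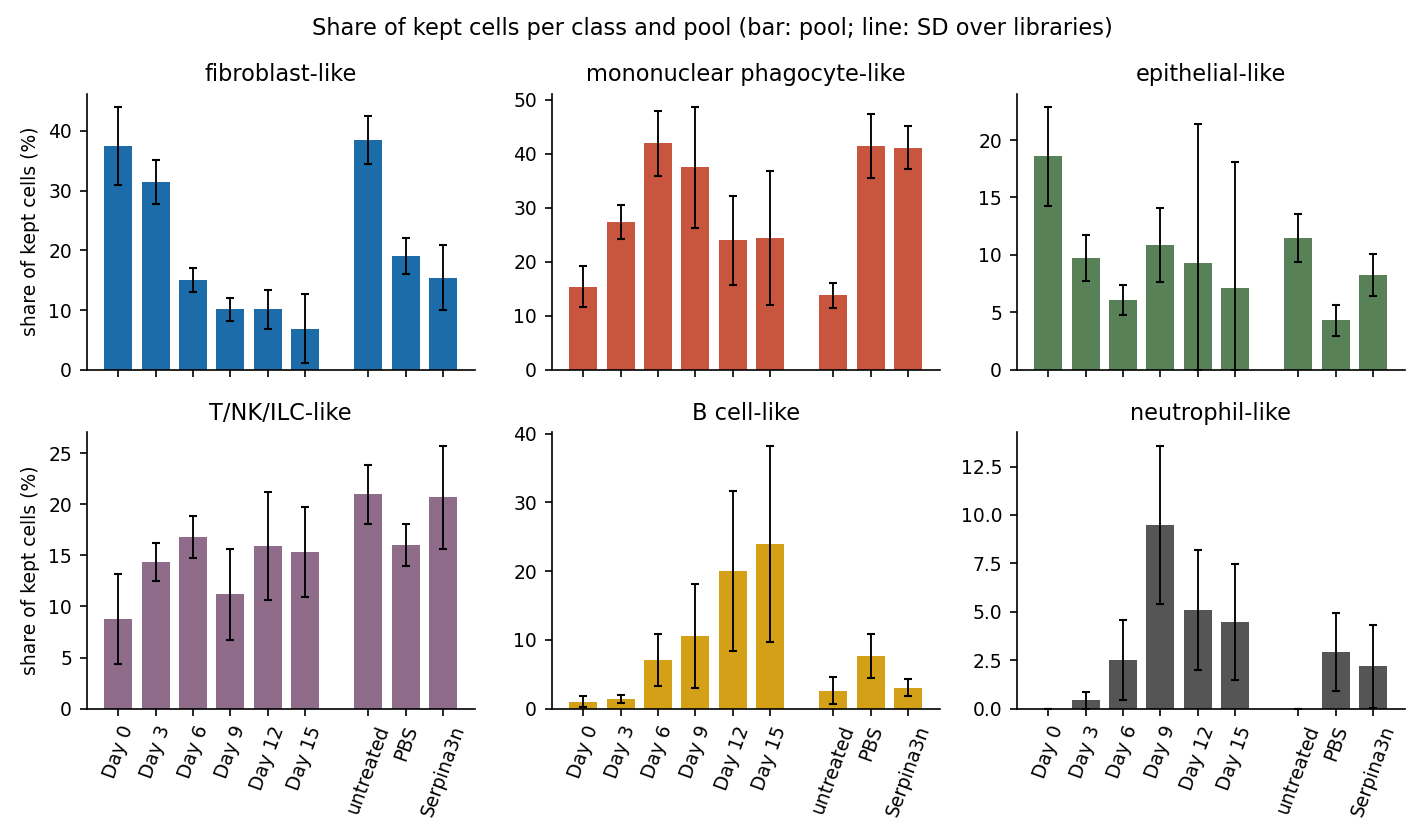
Share of kept cells (y axis, percent) in each of the 9 pools (x axis) for fibroblast, mononuclear phagocyte, epithelial, T/NK/ILC, B cell and neutrophil classes; each bar is 1 pool and each line the SD over its libraries, with the lower arm stopped at 0. Fibroblasts stood at 37.5% at Day 0 and 38.5% in the untreated pool against 15.0% at Day 6 and 19.1% in the PBS pool, and mononuclear phagocytes at 15.4% and 13.8% against 42.0% and 41.5%.

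The transcript of Serpina3n itself was most abundant in fibroblasts and was higher there in every DSS pool than in the pools without DSS. Mouse Serpina3n encodes a secreted inhibitor of serine proteases and lies on chromosome 12 from 104406729 to 104414329 on the plus strand (GRCm38, GENCODE M21, protein-coding gene ENSMUSG00000021091), in a cluster of related Serpina3 genes. In fibroblasts it stood at 260 CPM (counts of the class scaled to a common total) at Day 0 (Poisson 95% interval 237 to 285, library SD 79.1), 953 at Day 3, 2503 at Day 6 (2434 to 2574, SD 574), 3430 at Day 9 (3303 to 3560, SD 633), 1118 at Day 12 and 1544 at Day 15. Relative to Day 0 this was 3.66-fold (3.32 to 4.04), 9.61-fold (8.74 to 10.6), 13.2-fold (11.9 to 14.6), 4.29-fold (3.83 to 4.81) and 5.93-fold (5.30 to 6.65), each larger than the library spread. The PBS pool held 2215 CPM (2160 to 2272, SD 390) against 233 (215 to 252, SD 60.9) in the untreated pool, or 9.51-fold (8.75 to 10.3). In the pool injected with the Serpina3n protein the transcript stood at 1360 CPM (1300 to 1422, SD 454), which was 5.84-fold the untreated level and 0.614 of the PBS level (0.583 to 0.646), and the difference from PBS was not larger than the library spread. The untreated pool was at 0.895 of the Day 0 level (0.792 to 1.01).

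Smooth muscle and mural cells, the contractile cells of muscle layers and vessel walls, and endothelial cells also held the transcript after DSS. In the smooth muscle/mural class Serpina3n stood at 12.0 CPM at Day 0 from 3 counts, 671 at Day 6 (56.0-fold, 19 to 273) and 1329 at Day 9 (111-fold, 37.3 to 544), and at 702 CPM in the PBS pool against 2.57 from 1 count in the untreated pool (274-fold, 48.8 to 1.08e+04). All 3 counts of Day 0 lay in library 1 and the 1 count of the untreated pool in library 3. Without library 1 the log2 fold was 9.39 in place of 5.69 at Day 6 and 10.38 in place of 6.68 at Day 9, and without library 3 it was 9.46 in place of 7.62 for PBS, but these values are set by the pseudocount, since the baseline then holds 0 counts. The Serpina3n pool held 156 CPM in this class, 0.222 of the PBS level (0.166 to 0.292), and this difference was larger than the library spread. Cluster 27 held 23.5% of the smooth muscle/mural class at Day 0 and 51.3% at Day 9, so the mix of clusters differed here too. Endothelial cells held 0 counts at Day 0, 180 CPM at Day 6 (at least 7.76-fold higher, with the floor set at 3 counts) and 860 CPM at Day 9 (at least 37.1-fold). Cluster 16 held 25% of the endothelial cells of Day 0 and 61.5% of those of Day 9, so the mix of clusters differed. Epithelial cells held 40.9 CPM at Day 6, but library 6 gave most of it, since without this library the log2 fold was 1.98 in place of 5.39; at Day 9 it was 0.73 without library 1 in place of 4.89. In the immune classes the transcript did not exceed 10.4 CPM, the value of T/NK/ILC in the PBS pool from 10 counts. Neighbouring paralogs were also higher in Day 6 fibroblasts: Serpina3f at 102 against 0.556 CPM at Day 0, Serpina3g at 186 against 18.9 and Serpina3m at 94.1 against 3.34. Of the 40-base words of their last 1000 bases, Serpina3n shared 9.37% with other genes, Serpina3f 6.14%, Serpina3g 12.5% and Serpina3m 20.1%, so the values of Serpina3g and Serpina3m are uncertain. Serpina3m is also a leading gene of cluster 25, which held 0.139% of the fibroblasts at Day 0 and 21.4% at Day 6.

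**Figure D2:**
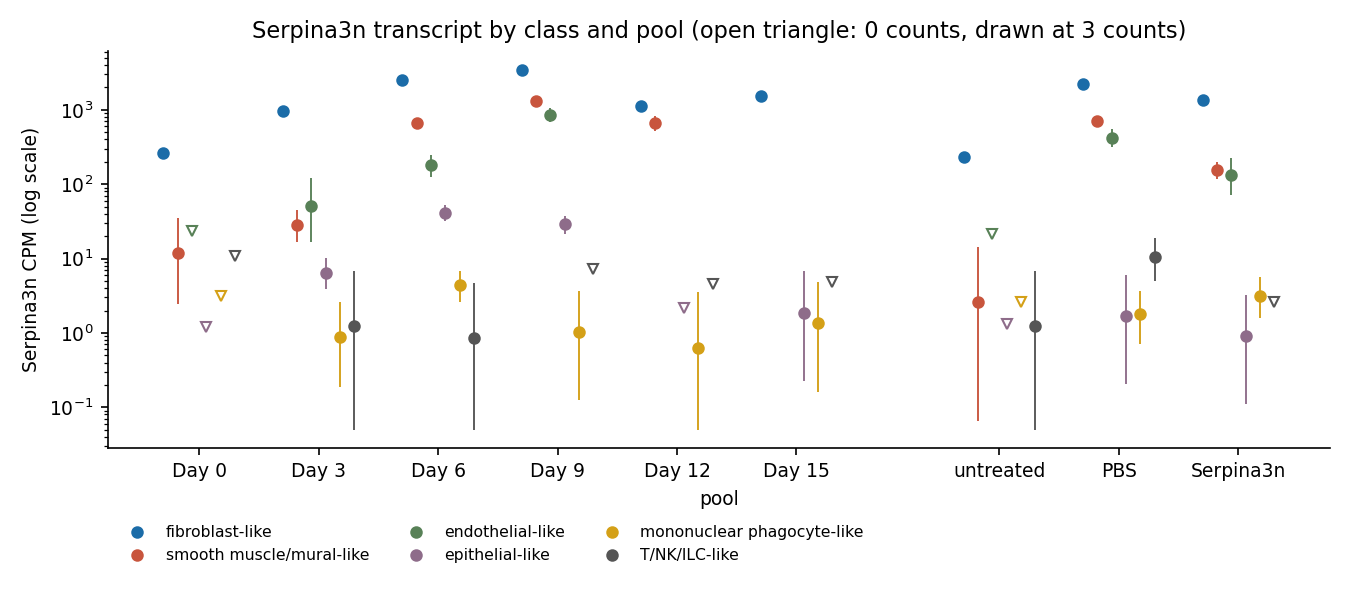
Serpina3n transcript (y axis, CPM on a log scale) by cell class and pool (x axis); each point is 1 pool, lines are exact Poisson 95% intervals drawn no lower than 0.05 CPM, and an open triangle marks 0 counts drawn at the level of 3 counts. Fibroblasts ran from 260 CPM at Day 0 to 3430 at Day 9, and smooth muscle/mural cells from 12.0 to 1329.

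In epithelial cells at Day 6 against Day 0 the interferon-inducible GTPase Iigp1 and the major histocompatibility complex (MHC) class II genes H2-Eb1 and Cd74, which present and guide peptide antigens, were higher. At both Day 6 and Day 9 the transglutaminase Tgm3, the ion transport regulator Fxyd4 and the sugar phosphate transporter Slc37a2 were lower. Tgm3 and Fxyd4 are among the leading genes of cluster 31, which held 66 cells at Day 0 and 0 at Day 6 and Day 9. Their class values therefore depend on the mix of clusters. At Day 9 the acute phase genes Saa3 and Lrg1 and Duoxa2, the maturation factor of the epithelial peroxide-producing oxidase, were higher. Where a pool holds 0 counts once a library is left out, the log2 fold is set by the pseudocount. Each gene given with a fold or as a member past the size rule met it: 2-fold or more, with a difference of library means larger than the sum of the 2 library SDs.

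At Day 6 Iigp1 was 24.6-fold higher in epithelial cells (95% counting interval 11.6 to 62.7), H2-Eb1 11.7-fold (7.03 to 20.7) and Cd74 6.82-fold (5.58 to 8.39). Their log2 folds were 5.18 in place of 4.20 for Iigp1 without library 7 of Day 0, and 4.15 in place of 3.37 for H2-Eb1 and 3.36 in place of 2.74 for Cd74 without library 3 of Day 0. The untreated pool held 20.5 CPM of Iigp1 and 13.1 of Cd74 against 2.81 and 48.2 at Day 0. Tgm3 was 75-fold lower (36.2 to 187), Slc37a2 66.3-fold lower (22.5 to 323, from 3 counts at Day 6), Fxyd4 at least 41.9-fold lower and Clca3, a secreted goblet cell protein, 51.7-fold lower (40.8 to 66.6). For Clca3 the log2 fold was -5.07 without library 6 of Day 0 and -8.54 without library 1 of Day 6 in place of -5.66, and the untreated pool held 374 CPM against 2246 at Day 0. For Slc37a2 it was -6.18 in place of -5.45 without library 6 of Day 6. Mptx1, a pentraxin-like gene of the intestinal epithelium, was 372-fold lower at Day 6 (180 to 926) and at least 1026-fold lower at Day 9, but 21.6% of its 3' words are shared with other genes, so its counts are uncertain. Its log2 fold at Day 6 was -7.58 without library 1 of Day 0 and -9.92 without library 10 of Day 6 in place of -8.24, and at Day 9 -10.01 without library 1 of Day 0 in place of -10.68. At Day 9 Saa3 was 199-fold higher (67.8 to 970) but its log2 fold was 3.76 in place of 6.77 without library 1 of Day 9. In the same pool Saa3 stood at 9884 CPM in fibroblasts and 13008 in mononuclear phagocytes. Beside this, collagens and matrix genes, typical of fibroblasts, had a median of 1.72 in the epithelial class at Day 6 (SD 2.98) and 2.27 at Day 9 (SD 2.87), with 0 of 15 members past the size rule at either day. Without library 6 of Day 6 and library 1 of Day 9 these medians were -0.31 and -0.91. Without library 2 of Day 0 they were 2.71 and 3.22, and against the untreated pool 2.90 and 3.13. With a pseudocount of 5 the Day 6 median was 1.06. Lrg1 was 93.5-fold higher at Day 9 (25.4 to 779, from 2 counts at Day 0) and Duoxa2 4.97-fold (3.81 to 6.55). Tgm3 was 124-fold lower at Day 9 (53.0 to 383), with a log2 fold of -7.27 in place of -6.50 without library 5 of Day 9.

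In epithelial cells the list of antimicrobial and acute phase genes had a median log2 fold of 1.69 at Day 6 (library SD of the median 1.46, 15 members) and 1.26 at Day 9 (SD 1.16, 14 members), above the library spread, although 0 and 2 members met the size rule. MHC class II and interferon-gamma response genes had a median of 1.57 at Day 6 (SD 1.67), with 4 of 17 members past the size rule, among them Cxcl9 at 22.7 CPM against 0 counts and Psmb8. That median was 2.20 without library 5 of Day 6 and 2.19 without library 7, and 2.22 with the ribosomal RNA rows left out of the totals. Mononuclear phagocytes of Day 6 held 10093 CPM of Cd74 and 5709 of H2-Eb1, against 329 and 79.9 in epithelial cells. Recruited monocyte genes had a median of 1.18 in the epithelial class at Day 6 (SD 1.91; 1 of 10 higher and 1 lower), or 0.73 as the mean over cells. Without library 6 of Day 6 that median was 0.09, and that of MHC class II and interferon-gamma response genes 1.60. Goblet and mucus genes had a median of -0.63 at Day 6 (SD 3.07), and 3 of 15 members were lower past the size rule, Reg4 at 25.2 against 480 CPM, Fcgbp and Klk1, the last 2 with 23.9% and 37.5% of their 3' words shared. Absorptive colonocyte genes had a median of -0.27 at Day 6 (SD 0.70), and 3 of 20 members were lower, among them the chloride anion exchanger Slc26a3 at 49.1 against 382 CPM. At Day 9 the median was 0.26 for MHC class II and interferon-gamma response genes (SD 1.09; 0 of 14 past the size rule) and -0.51 for goblet and mucus genes (SD 2.78; 1 of 15 lower), or 0.40 against the untreated pool. That of absorptive genes was 0.09 (SD 0.61; 2 of 20 lower). Day 0 epithelial cells lay mostly in clusters 8, 28 and 31, and those of Day 6 and Day 9 in clusters 8 and 28. Slc26a3 is a leading gene of cluster 31, so its class value depends on this mix. Between the untreated and Day 0 pools the antimicrobial median was -0.08 (SD 1.36) and the absorptive median -0.40 (SD 0.63).

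Fibroblasts of Day 6 had higher median levels of interferon response genes and of matrix proteases and their inhibitors than those of Day 0. At Day 6 and Day 9 the acute phase genes Saa3 and Hp and Cxcl5, a chemokine that attracts neutrophils, were among the largest differences, with the collagenase Mmp13 and the T cell chemokine Cxcl9 at Day 6 and the iron-sequestering Lcn2 at Day 9. The neuronal growth-associated gene Stmn2, the circadian genes Nr1d1 and Dbp, the matricellular gene Ctgf and the growth factor binding gene Igfbp6 were the lowest at Day 6.

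Saa3 stood at 3353 CPM at Day 6 and 9884 at Day 9 against 0 counts in Day 0 fibroblasts, at least 2009-fold and at least 5922-fold higher. Cxcl5 was 653-fold higher at Day 6 (117 to 2.58e+04, from 1 count at Day 0) and 363 CPM, and its log2 fold was 8.51 in place of 7.87 without library 7 of Day 0. Mmp13 was 167-fold higher (64.8 to 613), with 7.81 in place of 6.85 on the log2 scale without library 5 of Day 0. Cxcl9 was 205-fold higher (56.4 to 1696, from 2 counts), while the untreated pool held 18.5 CPM of it against 1.11 at Day 0. At Day 9 Lcn2 was 417-fold higher (115 to 3458, from 2 counts) at 464 CPM, against 9266 in neutrophils of that pool. Hp was 383-fold higher at Day 9 (105 to 3172, from 2 counts), with 8.74 in place of 7.66 on the log2 scale without library 3 of Day 0. Stmn2 was 77.4-fold lower at Day 6 (21 to 646), Nr1d1 22.6-fold (12.0 to 47.8), Ctgf 7.05-fold (5.49 to 9.17) and Igfbp6 6.14-fold lower (5.40 to 7.01). For these genes the untreated pool lay below Day 0, at 17.4 against 77.9 CPM for Stmn2, 35.9 against 114 for Nr1d1, 148 against 255 for Ctgf and 415 against 846 for Igfbp6.

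Among the fibroblast lists, MHC class II and interferon-gamma response genes had a median log2 fold of 2.21 at Day 6 (SD 1.56), and 11 of 19 members were higher past the size rule, among them Cxcl10 at 329 against 44.5 CPM. Type I interferon response genes had a median of 1.16 at Day 6 (SD 0.53), and 5 of 18 members were higher, such as the ubiquitin-like Isg15 at 109 against 17.8 CPM. Matrix proteases and their inhibitors had a median of 0.79 (SD 0.49), with 7 of 16 members higher and 1 lower, among them the stromelysins Mmp3 at 786 against 27.8 CPM and Mmp10 at 169 against 11.1. Collagens and matrix genes had a median of -0.41 (SD 0.21) against -0.15 for all genes, and 6 of 24 were lower, among them Postn at 1485 against 3868 CPM and Fn1 at 1118 against 2720, so the list as a whole is not read as lower. Epithelial niche factors, signals of fibroblasts to the epithelium, had a median of 0.51 (SD 0.41), with 5 of 21 members higher, such as the BMP inhibitor Grem1 at 923 against 146 CPM and the growth factor Nrg1 at 197 against 36.7. Inflammatory cytokines and chemokines had a median of 1.26 at Day 6 (SD 1.87) with 4 of 17 members past the size rule, and 1.29 at Day 9 (SD 2.66). Against the untreated pool the Day 6 median was 4.68 and the Day 9 median 3.12. Il6 stood at 94.0 CPM at Day 0 and at 0 counts in the untreated pool, and 4 of 12 members were lower past the size rule in the untreated pool than at Day 0. The dissociation and immediate early list, genes induced by tissue handling, was -0.44 at Day 6 (SD 0.58), 0.01 at Day 9 (SD 0.55) and -1.23 in the untreated pool against Day 0 (SD 0.59), with 7 of 20 members lower there. Day 0 fibroblasts lay in clusters 0, 1 and 2, and those of Day 6 in these and in clusters 25 and 29. Cluster 25 held 0.139% of the fibroblasts at Day 0 and 21.4% at Day 6, and cluster 29 held 0% and 18.9%. Cxcl5, Mmp3 and Mmp10 are among the leading genes of cluster 25, and Mmp10 and Nrg1 of cluster 29. Class values of these genes therefore depend on the mix of clusters. TMM scaling shifted the median of all fibroblast genes by 0.16 at Day 6 and 0.10 at Day 9.

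Mononuclear phagocytes of Day 6 and Day 9 had higher levels of genes of recruited monocytes and lower levels of genes of tissue-resident macrophages. At Day 6 the acute phase gene Saa3, the interferon-inducible membrane gene Ifitm1 and the monocyte gene Slfn4 were higher. At Day 9 the largest differences were Saa3, the calprotectin subunit S100a8, the protease inhibitor Slpi, Lcn2 and the inducible nitric oxide synthase Nos2. The fatty acid scavenger receptor Cd36 and the lipoxygenase Alox5 were among the lowest genes at Day 6, and Cd36 and the resistin-like gene Retnla at Day 9.

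Ifitm1 was 93.7-fold higher at Day 6 (56.8 to 168), and Saa3 and Slfn4 were at least 113-fold and at least 21.1-fold higher, from 0 counts at Day 0. At Day 9 Saa3 stood at 13008 CPM (at least 4158-fold higher), S100a8 at 570 (at least 182-fold), Lcn2 at 406 (at least 130-fold) and Nos2 at 327 (at least 105-fold). Neutrophils, of which Day 0 held none, had 62364 CPM of S100a8 and 9266 of Lcn2 at Day 9, and 2668 of Slpi, 246 of Nos2 and 146 of Saa3. The S100a8 and Lcn2 values of the class are therefore uncertain where neutrophil transcripts entered it. Slpi was 651-fold higher at Day 9 (223 to 3157, from 3 counts), with a log2 fold of 10.99 in place of 8.95 without library 5 of Day 0. Cd36 was 24.1-fold lower at Day 6 (20.0 to 29.2) and stood at 18.3 against 734 CPM at Day 9, and Alox5 was 29.5-fold lower at Day 6 (17.4 to 53.6), where the untreated pool held 66.6 CPM against 108 at Day 0. Retnla was 218-fold lower at Day 9 (127 to 410), with a log2 fold of -6.81 without library 5 of Day 0 and -9.03 without library 1 of Day 9 in place of -7.57. The macrophage genes Cd209f and Cbr2 were also lower at Day 6, by 55.6-fold and 24.2-fold, but 39.2% and 18.7% of their 3' words are shared with other genes, so their counts are uncertain. Without library 4 of Day 6 the log2 fold of Cd209f was -6.41 in place of -5.47, and against the untreated pool it was -4.48, and that of Cbr2 -3.56 in place of -4.55.

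The recruited monocyte list had a median log2 fold of 1.54 at Day 3 (SD 1.19), 3.48 at Day 6 (SD 1.79), 4.01 at Day 9 (SD 1.68), 3.35 at Day 12 (SD 3.08) and 2.99 at Day 15 (SD 1.69). At Day 6, 14 of 19 members were higher past the size rule, among them Vcan at 157 against 4.17 CPM. That median was 3.26 with members at 0 counts set to 3 counts, 4.31 without library 5 of Day 0, 4.33 without members sharing 3' sequence and 2.81 with a pseudocount of 5. At Day 9, 16 of 20 members were higher, among them Chi3l3 at 2330 against 22.9 CPM and the arginase Arg1 at 155 CPM against 0 counts. The resident macrophage list had a median of -0.20 at Day 3 (SD 0.46), -1.72 at Day 6 (SD 0.61), -1.86 at Day 9 (SD 0.76), -1.30 at Day 12 (SD 0.59) and -1.53 at Day 15 (SD 0.66). At Day 6, 15 of 21 members were lower, among them the folate receptor Folr2 at 24.6 against 518 CPM and the hyaluronan receptor Lyve1 at 28.9 against 484. Inflammatory cytokines and chemokines had a median of 1.19 at Day 6 (SD 0.58) and 2.51 at Day 9 (SD 0.64), where 13 of 21 members were higher, such as Cxcl3 at 633 against 4.17 CPM. Against the untreated pool these medians were 1.91 and 3.37. MHC class II and interferon-gamma response genes had a median of 1.16 at Day 6 (SD 0.52) and 0.63 at Day 9 (SD 0.57). Cxcl9 at 954 CPM against 165 was among 8 higher members at Day 6, and Cd74 at 7108 against 15321 was lower at Day 9. Hypoxia and glycolysis genes were at 0.60 (SD 0.60) and 1.10 (SD 0.67), and 1.97 at Day 9 against the untreated pool, and immediate early genes at 0.22 (SD 0.62) and 0.77 (SD 0.62). Most Day 0 cells of the class lay in clusters 4 and 5, and the largest cluster was 11 at Day 6 and 17 at Day 9. Saa3, Nos2, Slpi and Arg1 are leading genes of cluster 30, which held 0.339% of the class at Day 0 and 21.8% at Day 9. Retnla leads cluster 32, with 4.07% and 0%. Folr2, Cbr2 and Cd209f are leading genes of cluster 5, with 39.3% at Day 0 and 3.26% at Day 6. Class values of these genes therefore depend on the mix of clusters. TMM scaling shifted the median of all genes by 0.35 at Day 6 and 0.46 at Day 9, so these medians are to be read against such a shift.

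In the T/NK/ILC class few genes met the size rule between Day 0 and the DSS pools. The costimulatory receptor Tnfrsf4 was higher at Day 6 and Day 9, and the inhibitory receptor Ctla4 was higher at Day 9. The cytoskeletal scaffold gene Ahnak was lower at both. Tnfrsf4 was 4.64-fold higher at Day 6 (2.39 to 10.3) and 3.97-fold at Day 9 (1.94 to 9.16). Ctla4 was 5.52-fold higher at Day 9 (3.72 to 8.49), with a log2 fold of 3.28 without library 7 of Day 0 and 3.64 against the untreated pool in place of 2.45. Ahnak was 2.24-fold lower at Day 6 (1.97 to 2.55) and 2.39-fold lower at Day 9 (2.01 to 2.84). Tnfrsf4 and Ctla4 are among the leading genes of cluster 23, so their class values depend on the mix of clusters. Type I interferon response genes had a median of 1.17 at Day 6 (SD 2.29), or 0.75 with 0 counts set to 3, with 4 of 16 members higher past the size rule, and 0.20 at Day 9 (SD 2.67; 0 of 12). The T cell effector list had a median of 0.11 at Day 6 (SD 2.60) and 0.19 at Day 9 (SD 2.84), so a difference in this list was not distinguishable at this depth. Clusters 7, 3 and 10 held most of the class at Day 0, and clusters 7, 10 and 23 at Day 6 and Day 9. TMM scaling shifted the median of all genes of the class by 0.24 at Day 6 and 0.16 at Day 9.

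**Figure D3:**
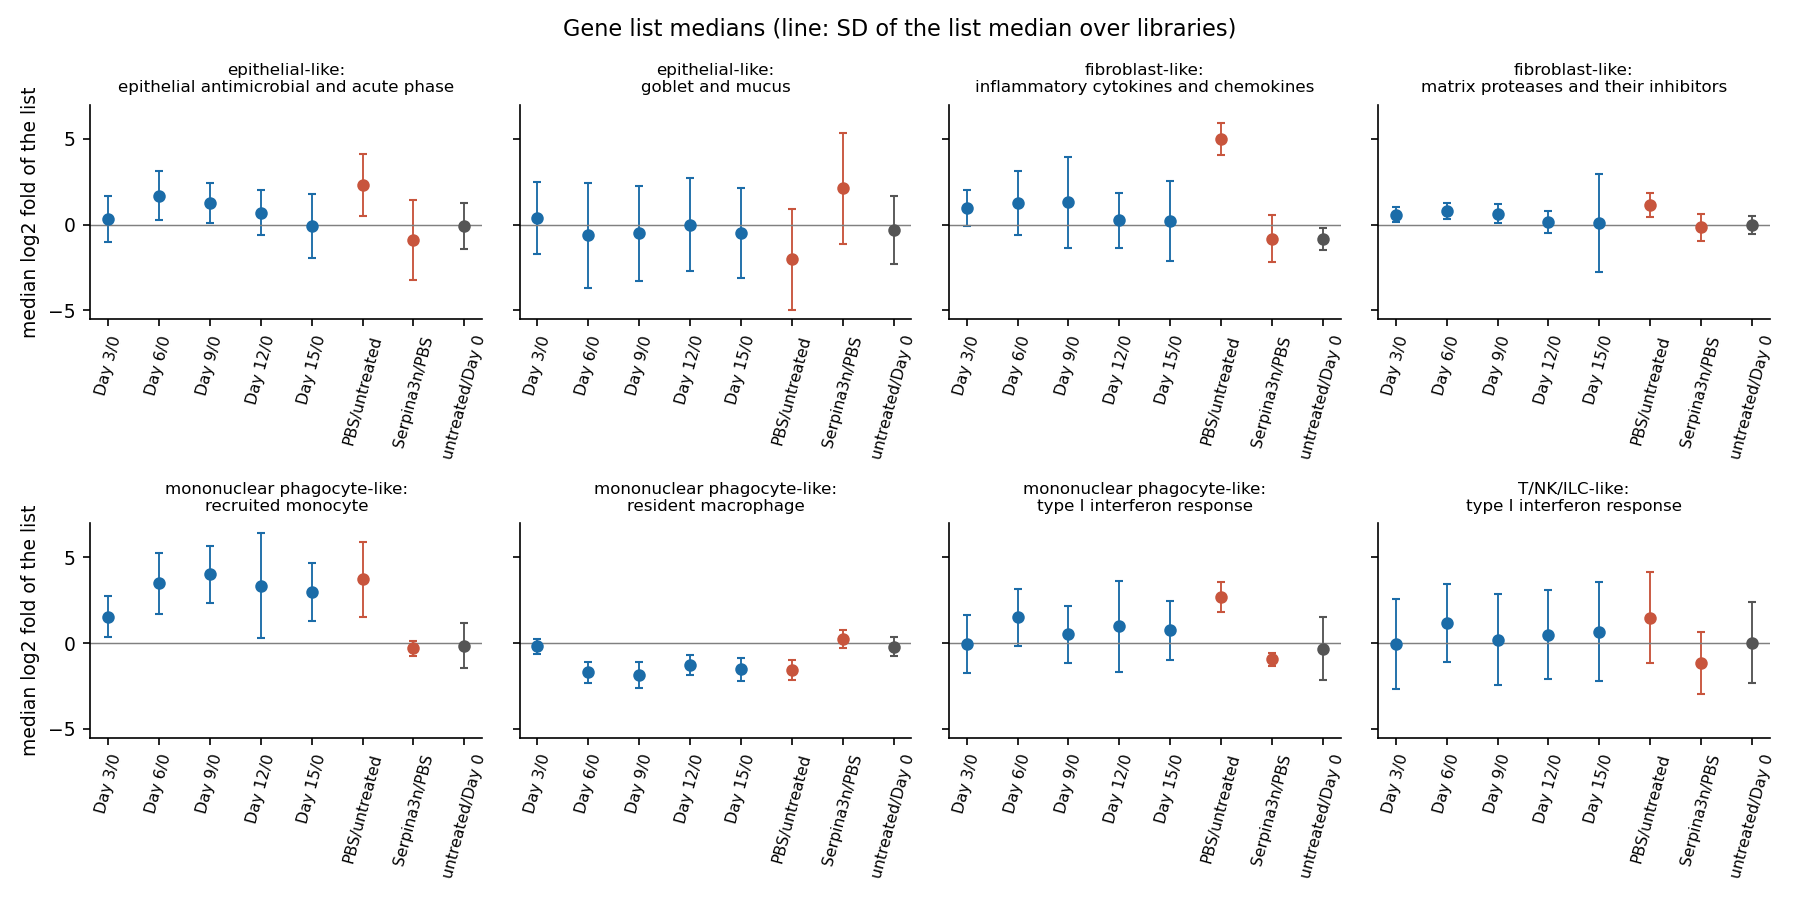
Median log2 fold of 8 gene lists (y axis) for each comparison (x axis); points are list medians and lines the library SD of the median, in blue for each day against Day 0, in red for PBS against untreated and Serpina3n against PBS, and in grey for untreated against Day 0. The resident macrophage median was -1.72 at Day 6 and -1.58 for PBS against untreated, and the type I interferon median of mononuclear phagocytes was 2.68 for PBS against untreated and -0.94 for Serpina3n against PBS.

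PBS against untreated asked how the pool with DSS and injections of PBS differed from the pool with neither. In epithelial cells the antimicrobial lectins Reg3b and Reg3g and the immunoproteasome subunits Psmb8 and Psmb9 were higher, and Slc37a2, Fxyd4 and the syncollin gene Sycn were lower. Fibroblasts had higher Saa3, Cxcl5, Lcn2, Hp and the cytokine Il6, and lower levels of the matrix-associated genes Aspn, Thbs2 and C1qtnf3. Mononuclear phagocytes had higher Saa3, Slpi, Hp and the matricellular gene Thbs1, and lower Cd36 and the platelet factor gene Pf4. In T/NK/ILC the cytokines Il17a and Ifng were higher and the chemokine Ccl5 was lower.

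Epithelial Reg3b stood at 11301 against 365 CPM, 30.9-fold higher (28.8 to 33.2), and Reg3g was 12.8-fold higher (11.5 to 14.2), with a log2 fold of 4.96 in place of 3.67 without library 7 of the untreated pool. Psmb9 was 4.90-fold (3.66 to 6.61) and Psmb8 4.82-fold higher (3.76 to 6.21). Slc37a2 was 275-fold lower (49.1 to 1.09e+04, from 1 count in the PBS pool), with -7.85 in place of -6.97 on the log2 scale without library 9 of that pool. Fxyd4 was 60.6-fold lower (16.6 to 503, from 2 counts) and Sycn 32.2-fold lower (23.6 to 44.9). The antimicrobial list had a median of 2.34 (SD 1.81, 14 members, 2 higher past the size rule), or 1.53 as the mean over cells, and immediate early genes a median of 1.16 (SD 1.11; 0 of 19 past the size rule), or 0.77 as the mean over cells. The median of MHC class II and interferon-gamma response genes was 2.14 (SD 2.65; 3 of 20 higher past the size rule and 20 above 0). That of recruited monocyte genes was 1.29 (SD 1.73; 0 of 8), or 0.54 without library 3 of the untreated pool, 2.84 as the mean over cells and 0.28 without members sharing 3' sequence. Goblet and mucus genes had a median of -2.03 (SD 2.94), or -1.43 as the mean over cells, with 2 of 15 members lower, the main mucin Muc2 at 319 against 1490 CPM and Klk1. Muc2, Zg16, Fcgbp and Tff3 are among the leading genes of cluster 13, so the goblet median depends on the mix of clusters. This cluster held 24 cells of the untreated pool and only 4 of the PBS pool. Most untreated epithelial cells lay in clusters 8 and 31, and most of the PBS pool in clusters 8 and 28. Fxyd4 and Sycn are leading genes of cluster 31, which held 51 cells of the untreated pool and 1 of the PBS pool. Their class values therefore depend on this mix too.

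Fibroblast Saa3 was at least 2308-fold higher in the PBS pool at 2618 CPM, Il6 at least 294-fold, Lcn2 at least 98.1-fold and Hp at least 83.1-fold, each from 0 counts in the untreated pool. Cxcl5 was 288-fold higher (123 to 889), with a log2 fold of 8.22 in place of 7.56 without library 5 of the untreated pool. C1qtnf3 was 10.3-fold lower (8.39 to 12.7), Aspn stood at 65.8 against 658 CPM and Thbs2 was 7.79-fold lower (6.36 to 9.62). Inflammatory cytokines and chemokines had a median log2 fold of 4.99 (SD 0.96), or 4.90 with 0 counts set to 3, with 14 of 18 members higher past the size rule, such as Cxcl1 at 623 against 6.05 CPM. Without library 1 of the PBS pool this median was 4.31, with a pseudocount of 5 it was 3.40, and with no filter on low expression 2.99. Beside it, immediate early genes had a median of 0.97 (SD 0.51) with 10 of 20 members higher. Against Day 0 the untreated fibroblasts had medians of -0.85 for the cytokine list and -1.23 for immediate early genes. Il6 was detected in Day 0 fibroblasts, as given above, so the size of the Il6 and cytokine differences depends on the baseline pool. MHC class II and interferon-gamma response genes had a median of 2.59 (SD 0.74; 13 of 18 higher, such as Gbp2 at 668 against 50.3 CPM) and type I interferon response genes 2.12 (SD 0.56; 12 of 19 higher). Matrix proteases had a median of 1.15 (SD 0.70; 6 of 16 higher, among them Mmp3 at 999 against 29.9 CPM). Collagens and matrix genes had a median of -0.45 (SD 0.18), with 4 of 24 lower, among them Postn at 1108 against 3505 CPM. PBS fibroblasts also held transcripts typical of immune cells, with Ifng at 75.4 CPM and Il17a at 106 CPM against 0 counts in the untreated pool and Il1b at 75 against 0.756. Untreated fibroblasts lay in clusters 0, 1 and 2, and most PBS fibroblasts in clusters 25 and 29.

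In mononuclear phagocytes of the PBS pool Thbs1 was 281-fold higher (110 to 1032), Saa3 at least 153-fold, Slpi at least 73.5-fold and Hp 199-fold higher (55.0 to 1646, from 2 counts). Cd36 was 11.8-fold lower (9.89 to 14.1), Pf4 9.52-fold lower (8.60 to 10.5) and Fcrls, an Fc receptor-like gene, 10.8-fold lower (8.71 to 13.5). For Cd36 the log2 fold was -4.20 in place of -3.53 as the mean over cells. Type I interferon response genes had a median of 2.68 (SD 0.87), with 19 of 20 members higher past the size rule, such as Isg15 at 440 against 22.5 CPM and Ifit1 at 73.0 against 4.33. MHC class II and interferon-gamma response genes had a median of 1.46 (SD 0.29), with 13 of 20 higher, such as Cxcl9 at 1276 against 20.8 CPM. The recruited monocyte median was 3.72 (SD 2.18; 15 of 20 higher), or 2.69 with 0 counts set to 3 and 2.65 with a pseudocount of 5, and the resident macrophage median -1.58 (SD 0.59; 11 of 21 lower, such as Lyve1 at 50.8 against 348 CPM). Inflammatory cytokines had a median of 2.22 (SD 1.88; 9 of 19 higher, such as Il1b at 3494 against 491 CPM), hypoxia and glycolysis genes 1.29 (SD 0.65; 10 of 17 higher) and immediate early genes 1.25 (SD 0.62; 10 of 20 higher). Of the hypoxia list, Gapdh shares 96.6% of its 3' words with other genes, Eno1 77.9% and Pgk1 56.5%. All genes with 50% or more shared had a median of 0.52 here against -0.12 for genes with none, so the hypoxia median is uncertain. Most untreated cells of the class lay in clusters 4 and 5, and the largest PBS cluster was 11. Saa3 and Slpi are leading genes of cluster 30, with 0% of the untreated and 9.70% of the PBS cells of the class. Thbs1 leads cluster 17, with 0.709% and 10.5%, and Pf4 and Fcrls are leading genes of cluster 5, with 32.6% and 4.96%. Class values of these genes therefore depend on the mix of clusters. TMM scaling shifted the median of all genes by 0.25.

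Ifng, the main activator of macrophages, stood at 1058 against 24.7 CPM in T/NK/ILC, 42.8-fold higher (27.6 to 70.4), but 18.4% of its 3' words are shared with other genes, and without library 1 of the PBS pool its log2 fold was 4.55 in place of 5.36 and with 1000 detected genes 6.25. Il17a, which drives neutrophil recruitment, was at least 82.3-fold higher at 305 CPM, with 6.02 in place of 8.26 on the log2 scale without library 4 of the PBS pool and 7.27 as the mean over cells. The barrier cytokine Il22 was at 504 CPM against 0 counts, with 45.1% of its 3' words shared, so its counts are uncertain. Ccl5 was 2.49-fold lower (2.35 to 2.64). The T cell effector list as a whole had a median of 0.31 (SD 2.67), with 4 of 19 members higher and 1 lower past the size rule, and proliferation genes 1.89 (SD 3.20; 4 of 20 higher, such as Hmgb2 at 173 against 37.1 CPM). Ifng and Il17a are also leading genes of clusters 26 and 3 of the class. The largest cluster of the class was 7 in the untreated pool and 10 in the PBS pool.

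Serpina3n against PBS asked whether the injected inhibitor altered the response. In epithelial cells, fibroblasts, mononuclear phagocytes and T/NK/ILC a smaller percent of genes differed by 2-fold or more than for PBS against untreated. Among genes at a mean of 20 CPM or more it was 0.834% against 14.9% in mononuclear phagocytes and 2.68% against 6.90% in epithelial cells. In fibroblasts it was 1.74% against 10.7%, and in T/NK/ILC 1.69% against 9.77%. Between the untreated and Day 0 pools it was 3.96% in mononuclear phagocytes, 3.07% in epithelial cells, 2.91% in fibroblasts and 11.5% in T/NK/ILC. Serpina3n against PBS thus lay below this yardstick of pools without DSS in each of these classes, as did PBS against untreated in T/NK/ILC. The B cell share differed by nearly as much for Serpina3n against PBS as for PBS against untreated, -4.61 against 5.09 percentage points. So did the median of goblet and mucus genes given below. However, goblet cluster 13 held only 4 cells of the PBS pool, against 18 of the Serpina3n and 24 of the untreated pool. In mononuclear phagocytes the pool injected with Serpina3n had lower levels of type I interferon response genes, among them the antiviral gene Rsad2 and the transcription factor Irf7. Its fibroblasts had higher levels of the matrix-associated genes Ctgf, Igfbp6 and Aspn, which were lower in the PBS pool than in the untreated pool, and lower levels of the cell adhesion gene Chl1 and the protease gene Pappa2. Cd36 was higher in its mononuclear phagocytes, and Cd44, a hyaluronan receptor, in its epithelial cells.

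In mononuclear phagocytes type I interferon response genes had a median log2 fold of -0.94 (SD 0.37), with 5 of 20 members lower past the size rule. Rsad2 was 2.72-fold lower (2.25 to 3.31), and Isg15 stood at 181 against 440 CPM, Irf7 at 110.5 against 257 and the oligoadenylate synthetase-like Oasl2 at 88.0 against 191. The same list was -0.56 in fibroblasts (SD 0.69; 1 of 20 lower, Irf7, 2.82-fold, 2.02 to 4.02) and -1.16 in T/NK/ILC (SD 1.82; 0 of 17 past the size rule), both within the library spread. Between the untreated and Day 0 pools it was -0.32 in mononuclear phagocytes (SD 1.83), -0.13 in fibroblasts (SD 0.44), 0.01 in T/NK/ILC (SD 2.37) and -0.66 in epithelial cells. MHC class II and interferon-gamma response genes of mononuclear phagocytes had a median of -0.36 (SD 0.24) with 0 of 20 members past the size rule. Recruited monocyte genes were at -0.31 (SD 0.42; 2 of 20 lower, Chi3l3 at 402 against 884 CPM and Ly6c2, of whose 3' words 43.9% are shared) and resident macrophage genes at 0.24 (SD 0.52; 0 of 20), both within the library spread. Slfn4 was 2.82-fold lower (2.29 to 3.49), and Cd36 2.12-fold higher (1.75 to 2.57) at 89.1 against 42.1 CPM, with 496 in the untreated pool. The largest cluster of the class was 11 in both pools.

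Fibroblast Ctgf was 3.44-fold higher in the Serpina3n pool than in the PBS pool (2.73 to 4.35), Igfbp6 2.78-fold (2.37 to 3.27) and Aspn 2.78-fold (2.29 to 3.38), and their untreated levels were 148, 415 and 658 CPM against 147, 263 and 183 in the Serpina3n pool. Pappa2 was 6.81-fold lower (4.10 to 12.1), Chl1 3.09-fold (2.46 to 3.93) and the guanylate-binding gene Gbp5 3.02-fold lower (2.27 to 4.07). Inflammatory cytokines and chemokines had a median of -0.84 (SD 1.37; 0 of 18 past the size rule) and MHC class II and interferon-gamma response genes -0.80 (SD 1.11; 1 of 19 lower, Psmb8 at 175 against 357 CPM), both within the library spread. So were collagens and matrix genes at 0.12 (SD 0.27), matrix proteases -0.17 (SD 0.79; 1 of 16 lower, Timp3 at 1147 against 2816 CPM) and epithelial niche factors 0.02 (SD 0.61). Immediate early genes were at -0.05 (SD 0.79). Most Serpina3n fibroblasts lay in clusters 0, 1 and 2, and most PBS fibroblasts in clusters 25 and 29. In epithelial cells Cd44 was 2.04-fold higher (1.64 to 2.55), and goblet and mucus genes had a median of 2.11 (SD 3.23; 0 of 15 past the size rule), or 2.72 without library 5 of the PBS pool. This median too depends on how much of each pool lay in cluster 13, which held 18 cells of the Serpina3n pool and only 4 of the PBS pool. Antimicrobial genes had a median of -0.92 (SD 2.35), or -0.29 without library 6 of the PBS pool and -1.60 without library 1 of the Serpina3n pool. In T/NK/ILC the cytokine signalling inhibitor Socs3 was 2.95-fold lower (1.91 to 4.66).

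The Serpina3n pool was also set against the untreated pool, which serves PBS against untreated as well. In fibroblasts the medians were 3.50 for inflammatory cytokines (SD 1.20; 6 of 17 higher past the size rule), 1.89 for MHC class II and interferon-gamma response genes (SD 1.07; 8 of 18 higher) and 1.38 for type I interferon response genes (SD 0.62; 7 of 18 higher). In mononuclear phagocytes they were 3.29 for recruited monocyte genes (SD 2.19; 15 of 20 higher), or 2.37 with 0 counts set to 3, -1.36 for resident macrophage genes (SD 0.42; 11 of 21 lower) and 1.61 for type I interferon response genes (SD 0.79; 11 of 19 higher). In T/NK/ILC the type I interferon median was 0.04 (SD 0.52; 1 of 12 higher) where that of PBS was 1.48 (SD 2.67; 0 of 17). In epithelial cells the median was 2.01 for MHC class II and interferon-gamma response genes (SD 1.62; 10 of 20 higher). Beside it that of immediate early genes was 1.53 (SD 0.89; 10 of 19 higher). For PBS against untreated the MHC class II median was 2.14 (SD 2.65; 3 of 20 higher). For Serpina3n against PBS it was 0.04 (SD 2.17; 0 of 21), running from -0.07 without library 8 of the PBS pool to 0.29 without library 6 of that pool. The goblet and mucus median was 0.16 (SD 2.35; 0 of 15), or -0.46 without library 1 of Serpina3n, and the antimicrobial median 0.74 (SD 1.87; 2 of 11 higher), or 0.08 without that library and 1.75 without members sharing 3' sequence. TMM scaling shifted the median of all mononuclear phagocyte genes by 0.22 in this comparison.

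The gene differences of PBS against untreated were set beside those of each day against Day 0, to see which day of the time course the treatment pool resembled. Across genes of mononuclear phagocytes, Spearman's rank correlation was 0.397 at Day 3, 0.594 at Day 6, 0.592 at Day 9, 0.547 at Day 12 and 0.474 at Day 15. In fibroblasts it was 0.431, 0.452, 0.388, 0.164 and 0.0129 at the same days, in epithelial cells 0.220, 0.205, 0.312, 0.259 and 0.151, and in T/NK/ILC 0.0730, 0.101, 0.119, 0.12 and 0.00705. Pearson's r for mononuclear phagocytes was 0.782 at Day 6 and 0.773 at Day 9, and for fibroblasts 0.699 and 0.616. These values used genes at a mean of 20 CPM or more, and the day with the highest rank correlation depended on that cutoff. At a mean of 100 CPM it was Day 3 in fibroblasts and Day 9 in mononuclear phagocytes, in place of Day 6. The closest day is therefore not settled. The compared differences shared no library, and genes are not independent replicates, so no p-value is given. The day on which the treatment pools were collected is not given in the sources used here.

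**Figure D4:**
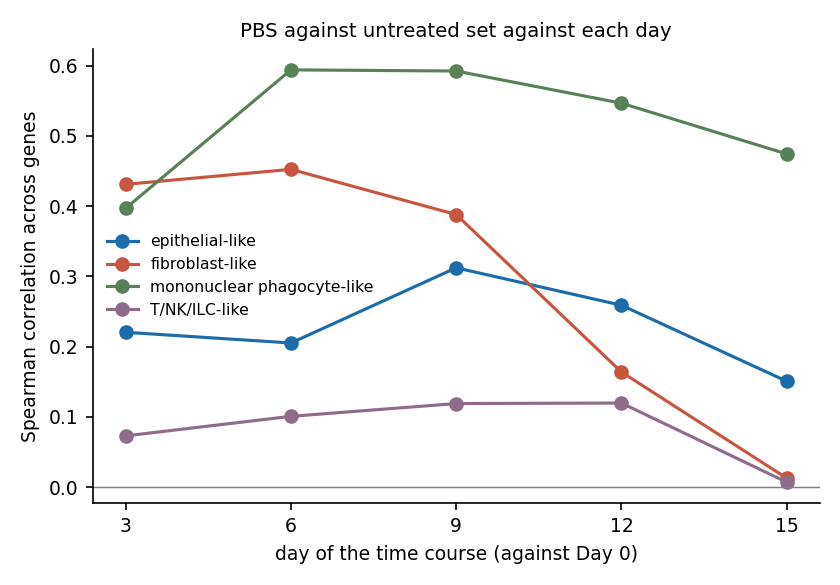
Spearman's rank correlation across genes (y axis) between PBS against untreated and each day against Day 0 (x axis, days) for 4 cell classes; each point is 1 correlation, with no error bar. Mononuclear phagocytes ran from 0.397 at Day 3 to 0.594 at Day 6, and fibroblasts stood at 0.452 at Day 6 and 0.0129 at Day 15. Genes at a mean of 20 CPM or more were used.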

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

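The test of all genes lower in the untreated pool, the cluster tests in fibroblasts and T/NK/ILC, and the run, handling and mild inflammation tests were chosen only after the result was seen.

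Single libraries stood apart from the others of their pool in 14 cases among 87 groups tested, against about 4.35 by chance. That chance value holds for normally distributed values, and some groups were mostly 0. The PBS pool held 1 plasma cell in all. Serpina3n counts of smooth muscle/mural cells lay in 1 library at Day 0 and in the untreated pool. A library stood apart there in any case, but this covers only these groups and not the other cases. Whether the other cases mark faulty libraries was not tested. Serpina3n in smooth muscle/mural cells was 73.9 CPM in library 1 of Day 0, 94.5 in library 3 of Day 3 and 15.4 in library 3 of the untreated pool. Mononuclear phagocytes were 19.9% of library 6 of Day 3, B cells 2.80% of library 10 of Day 3, and neutrophils 1.42% of library 8 of Day 3. T/NK/ILC were 0% of library 10 of Day 9 and 1.85% of library 4 of Day 12, whose epithelial share was 46.3%. Library 1 of Day 15 held 22.7% fibroblasts and 40.9% epithelial cells. Plasma cells were 0.380% of library 2 of PBS and 0.889% of library 3 of the untreated pool, and B cells 0% of library 8 of Serpina3n. Of these, library 10 of Day 9, library 4 of Day 12 and library 1 of Day 15 held only 26, 54 and 22 kept cells.

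Cells without a class name were 0.885% of Day 15, with a lower interval bound of 0.517%, against 0.209% of Day 0. The criterion, a lower bound above the Day 0 value, was set after a stricter version, above the upper bound of Day 0 at 0.533%, had picked out nothing. Lists and named genes were compared in 3123 pairs, between days within a class or between classes within a comparison. In 0 pairs did every library of 1 effect lie higher and every library of the other lower than the baseline, and shares were not part of this comparison.

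Eef1a1, which carries transfer RNA to the ribosome, and Rps4x, Btf3 and Eno1 were lower in the untreated pool than in the Day 0 pool. Reads shared with near-identical transcripts could explain this if they were counted differently between runs. Genes with 50% or more of their 3' words shared include Eef1a1 and Eno1 themselves. Their median log2 difference was -0.33 in the class where it was smallest in size, which did not decide the question. Of the 20 genes lower in all 4 main classes, 90% share 10% or more of their words, against 8.93% of 3865 measured genes. Most of the 20 are ribosomal protein genes, and Eef1a1, Btf3 and Eno1 are among them. Of ribosomal protein genes measured in epithelial cells, 11 shared under 10% of their words and 19 shared 50% or more. This comparison with all genes therefore cannot tell shared reads from lower translation machinery. Lower translation machinery as a whole was the other explanation, and a gap of 0.39 between the groups of genes left it open.

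Type I interferon response genes were lower in the pool injected with Serpina3n than in the PBS pool, with a median log2 fold of -0.94 in mononuclear phagocytes. A different mix of clusters could cause part of this, since the medians of the 7 clusters, from -0.87 to -0.30, all lay nearer to 0 than that of the class. A median at least 50% as low as the class median was found in 5 of 7 clusters there and 3 of 4 of T/NK/ILC. In fibroblasts this was so in 1 of 4 clusters, so the mix may explain the class value there. In mononuclear phagocytes and T/NK/ILC a mix of these clusters is less likely as the whole cause. A finer mix within the clusters was not tested, so a change in cell mix is not excluded. At a resolution of 2.0, a cluster of 282 mononuclear phagocytes had Mx1, Isg15, Ifit2 and Irf7 among its leading genes. A difference between runs or pools could also cause this, since each of these pools has its own run. Between the untreated and Day 0 pools the same list was -0.66 in epithelial cells, -0.32 in mononuclear phagocytes, -0.13 in fibroblasts and 0.01 in T/NK/ILC, where the Serpina3n pool differed from PBS by -0.55, -0.94, -0.56 and -1.16. An effect of the injected inhibitor cannot be told apart from it with 1 pool per group.

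Il6, Cxcl1 and Ccl2, inflammatory mediators of fibroblasts, were higher in the Day 0 pool than in the untreated pool. A response to tissue handling at Day 0 could explain this, and immediate early genes were lower in the untreated pool in each class, by -0.33 on the log2 scale in the least affected class, which did not decide it. Mild inflammation of the Day 0 mice is less likely, since recruited monocyte genes of mononuclear phagocytes differed by only -0.15 and Saa3 held 0 counts in Day 0 fibroblasts.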

How the results depend on the processing

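No paired analysis was possible because each group is 1 pool and libraries that carry the same number in different groups share no mice; the results come from no test. The use of the 10% bound on shared sequence, the lead lists, the definition of a list difference, the tolerance of 0.1 on rank correlations, the removal of libraries under 60 kept cells and of 5 ribosomal RNA rows were chosen after the data had been seen. Where values moved or reversed, the cause was not tested.

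A list median or gene fold counted as unmoved where it stayed within its library spread, which is wide for genes with few counts and for the lists of T/NK/ILC. By this measure the untreated pool as baseline moved 33 of 499 list medians, the lack of a low-expression filter 19 of 920, a pseudocount of 5 moved 9 of 920 and TMM scaling 4 of 916. A pseudocount of 5 moved 22 of 137 named genes and the untreated pool as baseline 8 of 73, and many gene folds that stayed within the spread still moved by more than 1.5 times without a single library.

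With cells of the same compartment as denominator, the difference in share of fibroblast was -10.3 in place of -22.5 percentage points at Day 6, -13.7 in place of -27.4 at Day 9, and -5.60 in place of -19.4 for PBS against untreated. That of mononuclear phagocyte was 12.2 in place of 26.6 at Day 6 and 4.89 in place of 22.1 at Day 9. That of T/NK/ILC reversed to -2.96 from 8.02 at Day 6 and to -11.1 from 2.41 at Day 9, and was -32.0 in place of -4.98 for PBS.

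With 1000 detected genes the difference in share of epithelial was -17.7 in place of -12.5 at Day 6 and -10.2 in place of -7.20 for PBS, and that of T/NK/ILC for PBS reversed to 1.91. For B cells it was 0.597 at Day 6, 0.405 at Day 9, 0.961 for PBS and -0.964 for Serpina3n against PBS, in place of 6.11, 9.56, 5.09 and -4.61. For neutrophils it was 0.0568 at Day 6, 1.71 at Day 9 and 0 for PBS in place of 2.51, 9.48 and 2.93, and with no cell filter 4.90 at Day 6 and 6.62 for PBS.

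The list median of inflammatory cytokines and chemokines in fibroblast was 4.68 at Day 6 with the untreated pool as baseline in place of 1.26. For PBS against untreated it was 3.40 with a pseudocount of 5 and 2.99 with no low-expression filter in place of 4.99. Complement in fibroblast at Day 9 reversed to -0.0807 from 0.78 without members sharing 3' sequence. For Serpina3n against untreated in fibroblast, resident macrophage genes reversed to -0.0887 from 0.86 without Scrublet doublets and ran from -0.0411 without library 4 of Serpina3n to 0.940 without library 3 of the untreated pool. In the same comparison hypoxia and glycolysis genes reversed to -0.0980 from 0.45 without members sharing 3' sequence.

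The rank correlation across genes as the mean over cells was 0.0977 at Day 3 and 0.208 at Day 9 in epithelial cells, 0.220 at Day 9 in fibroblasts and -0.0102 at Day 15 in T/NK/ILC, where it reversed. At a mean CPM of 100 it was 0.457 at Day 12 in epithelial cells. In fibroblasts it was 0.649 at Day 3, 0.623 at Day 6, 0.572 at Day 9 and 0.270 at Day 12. In mononuclear phagocytes it was 0.562, 0.707, 0.714, 0.687 and 0.610 over the 5 days, and in T/NK/ILC -0.0673 at Day 15.

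Leaving out 1 library, the log2 fold of Serpina3n in smooth muscle/mural ran from 0.83 to 4.86 at Day 3 around 1.16, from 5.44 to 9.39 at Day 6 around 5.69, from 6.23 to 10.38 at Day 9 around 6.68, and from 7.37 to 9.46 for PBS against untreated around 7.62.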

Other observations

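Smooth muscle and mural cells also had higher levels of interferon response genes after DSS. MHC class II and interferon-gamma response genes had a median log2 fold of 2.90 at Day 6 (library SD 0.86; 9 of 17 members past the size rule), or 3.49 without library 2 of Day 0, and 3.17 for PBS against untreated (SD 2.26; 9 of 17), or 4.16 without library 8 of the untreated pool. Gbp2, a guanylate-binding protein gene induced by interferon-gamma, stood at 1365 against 75.9 CPM at Day 6 and at 1760 against 43.6 for PBS. Type I interferon response genes had a median of 2.57 at Day 6 (SD 1.28; 10 of 16), or 3.29 with 1000 detected genes.

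The circadian repressor Nr1d1 stood in fibroblasts at 114 CPM at Day 0, 40.6 at Day 3, 5.03 at Day 6, 4.97 at Day 9, 15.4 at Day 12 and 25.6 at Day 15, and at 35.9 in the untreated pool, 7.76 with PBS and 19.6 with Serpina3n. The 2 pools without DSS thus differed in Nr1d1 from each other, and the hour of collection is not given in the sources used here.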
